A study of Mus musculus with 55 samples.

How the data were processed

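The series held 55 mouse samples, of which 12 RNA libraries and 26 peak libraries had files that were analysed. Whole-genome bisulfite, single-cell RNA, S-adenosylmethionine treatment and IgG data are not analysed here. Each RNA group held 3 libraries and each peak group 2. The labels do not say that replicates came from separate animals, so each p-value of a single gene measures the spread between these samples. Fisher and permutation tests run across genes or regions, and their p-values measure no spread between samples. The labels leave other points open. The PRMK RNA samples list no guide against Kmt2c among their plasmids. The PRM RNA columns are numbered 4 to 6, while the titles number these samples 3 to 5. A stranded kit is named only for the PRM RNA samples, so a difference in library preparation cannot be told apart from genotype. Replicate 1 of the PRMK H3K4me2, H3K4me3 and KMT2C samples lists a guide against Meis2 and replicate 2 a scrambled guide, so each PRMK pair of these marks mixes both.

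The authors aligned RNA reads with STAR 2.6.0a to GRCm38, and the deposited values analysed were raw counts per gene. The deposited tables also held log2 fold changes with their standard errors, and p-values with adjusted p-values, all computed by the authors, who name DESeq2 among their tools. The authors aligned ATAC reads with Bowtie2 2.2.1 to mm10, and each deposited peak carries the score its caller wrote. The caller is not given in the sources used here. The authors aligned CUT&Tag reads with Bowtie2 to mm10 and called peaks with SEACR, and the deposited lists give the total and highest signal over each peak, with no depth stated. The control used for calling is not given in the sources used here.

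RNA counts were analysed in R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1. The main test was the edgeR quasi-likelihood test after TMM normalization and edgeR's filter on low counts, with a Benjamini-Hochberg adjusted p under 0.05. It covered 13914 genes in PRMK versus PRM and 16260 in sgMeis2 versus sgScramble. The deposited tables of both comparisons were made separately and were not pooled. CPM were scaled by TMM, and levels are means with SD over 3 libraries. Genes with no counts in a group were given a lower bound against a floor of 3 counts over the group. Total counts of 12013253 to 24389041 per library set the depth, and intervals and floors cover counting error only. Of the genes in the sgMeis2 table, 24781 had no symbol, and 24552 received one from the reference by gene ID.

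A fixed set of 31 gene lists, covering cell types, pathways, complexes and the drivers, was tested with camera at a preset correlation of 0.01, over lists with 4 or more members tested. Members were matched by symbol and by gene ID. Matching by gene ID was added after the first list results were seen, because no mitochondrially encoded gene matched by symbol, and matching by symbol alone was kept as an alternative. Tests, lists and most alternatives were chosen before the data were examined. The genes to name were set by rule: the drivers, the 8 largest and 8 smallest log2 fold changes among called genes with a mean of 1 CPM or more and no overlap between groups, and up to 3 called members of each list. Since edgeR called none, the rule was applied to DESeq2 calls. Genes with the lowest edgeR p were added after their values were seen.

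Peak lists were analysed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. For each comparison the 4 peak lists were merged into union regions. A region was gained or lost when both libraries of one group and neither of the other had a peak over at least 1 bp, and kept when all 4 had one. With 2 libraries against 2 there are 6 labelled arrangements and 3 splits, so an exact permutation test cannot give a p under 0.333. No test was made, and the count is set beside those of the other splits. KMT2C on lost and kept H3K4me1 regions was compared by a 2-sided Fisher exact test. Median log2 fold changes of genes by promoter H3K4me3 (1 kb around either gene end) or nearby H3K4me1 (gene and 10 kb) were compared by 2-sided permutation tests with 100000 resamples, over 13872 genes with coordinates on GRCm38. Clustering of expression by chromosome was tested with 10000 permutations over genes of at least 10 CPM.

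The tools were tested on simulated data. Counts were drawn with a single spread per gene, shared by all libraries of a comparison, so no group or library was noisier than another. In data modelled on PRMK versus PRM, 200 genes were changed. There edgeR recovered 0 of 70 genes at 2-fold, 10 of 70 at 4-fold and 40 of 60 at 16-fold, and DESeq2 4, 34 and 57. In data modelled on the sgMeis2 comparison edgeR recovered 53, 58 and 60 and DESeq2 56, 58 and 60. The largest fold was added after an earlier run, not the one given here, in which edgeR recovered none of 200 genes changed by the smaller folds. All 300 gained, 200 lost and 1000 kept simulated regions were recovered.

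Alternatives were DESeq2, DESeq2 size factors in edgeR, no filter, a mean of at least 5 CPM, a fold of at least 2, an estimated correlation, each library left out, the replicate number as a block for sgMeis2 versus sgScramble, the upper part of each peak list by signal or score, a reciprocal overlap of 0.5, narrow blocks within ATAC peaks, KMT2C peaks in either library, a 2.5 kb promoter and the gene body alone. Chosen after seeing the data were robust dispersions, the edgeR likelihood ratio test, limma-voom with library weights, DESeq2 with each library left out, symbol matching, DESeq2 calls for the genes in both comparisons, region width deciles, genes without clustered protocadherins, and RNA libraries left out of the promoter tests. The 36 columns of other sample values in the count tables were not used.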

Results

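The series held 55 mouse samples from organoid-derived small cell lung cancers. The tumour genotypes are named PRM, for edited Trp53 and Rb1 with expressed Myc, and PRMK, for PRM with an added guide against Kmt2c, which encodes an H3K4 methyltransferase. Expression was measured by RNA sequencing in 12 libraries, 3 per group: PRMK, PRM, PRMK with a guide against Meis2 (sgMeis2) and PRMK with a scrambled guide (sgScramble). Peak lists came from 26 libraries in 13 groups of 2, for open chromatin (ATAC) and for H3K4me1, H3K4me2, H3K4me3 and KMT2C by CUT&Tag, an antibody-directed cleavage assay. They covered lung PRM and lung PRMK for all 5 measurements, and liver PRM for ATAC, H3K4me1 and KMT2C. Total counts were 23554257, 18819262 and 24123055 in PRMK libraries 1 to 3, 18447615, 19550439 and 12013253 in PRM libraries 4 to 6, 19023698, 22012962 and 18524493 in sgMeis2 libraries 1 to 3, and 21520703, 21228986 and 24389041 in sgScramble libraries 1 to 3. The depth of the peak libraries was not given.

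In order to determine which transcripts differ between tumours labelled PRMK and PRM, their RNA libraries were compared. The plasmids listed for these PRMK samples include no guide against Kmt2c, so whether Kmt2c was edited in them is open. Kmt2c itself (ENSMUSG00000038056) was at 91.4 ± 11.5 CPM (counts per library total, scaled by TMM; SD, n = 3) in PRMK and 122 ± 60.1 in PRM, a log2 fold change of -0.42 (SE 0.38) by edgeR, smaller than the spread between the PRM libraries, and 0.02 without PRM library 5. Meis2 (ENSMUSG00000027210), a homeobox transcription factor, was at 208 ± 66.5 CPM in PRMK and 6.54 ± 9.30 in PRM. The highest PRM library held 17.3 CPM and the lowest PRMK library 139. Myc (ENSMUSG00000022346), the expressed oncogene, was at 263 ± 54.0 CPM in PRMK and 1835 ± 614 in PRM, lower in all 3 of 3 PRMK libraries than in any PRM library. Neurod1, a neurogenic transcription factor, was at 0.614 ± 0.446 CPM in PRMK and 47.1 ± 50.0 in PRM.

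For Meis2 the log2 fold change was 5.02 (SE 1.254), with an adjusted p of 0.195 by edgeR and 2.15e-04 by DESeq2. Without PRM library 6 it was 7.47. For Myc it was -2.80 (SE 0.36), with an adjusted p of 0.158 by edgeR and 1.57e-10 by DESeq2. The edgeR quasi-likelihood test, chosen as the main test, called 0 of 13914 genes. It gave 2384 genes an unadjusted p under 0.05, 978 higher and 1406 lower in PRMK, and its lowest adjusted p was 0.158. DESeq2 called 1218 genes, 542 higher and 676 lower, and the edgeR likelihood ratio test called 454. DESeq2 called 215 without PRMK library 1, 128 higher and 87 lower, and 4060 without PRM library 4. In simulated data with a single spread per gene, shared by all libraries, 98 of 193 DESeq2 calls were false (50.8%), against 5 of 55 by edgeR (9.09%). The real PRM libraries were less alike (Pearson r of log2 CPM 0.778 to 0.863 between pairs) than the PRMK libraries (0.937 to 0.971). The simulation did not copy this, so its error shares need not hold here. These shares depend on how many genes the simulation changed, so they do not estimate the false share among the 1218 DESeq2 calls. DESeq2 made more false calls than edgeR in the same simulated data. Single genes that DESeq2 alone called are values with an uncertain call, since the main test did not call them. Without PRM library 4, edgeR called 796 genes, 282 higher and 514 lower, of which 418 were among the DESeq2 calls. The authors' table gave 993 genes an adjusted p under 0.05, and 887 of them were also called by DESeq2 here.

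The other driver genes were not called by either tool. Dnmt3a, a DNA methyltransferase, was at 334 ± 6.46 CPM in PRMK and 186 ± 73.2 in PRM, with no overlap between the groups and a log2 fold change of 0.85 (SE 0.34; adjusted p = 0.281 by edgeR, 0.159 by DESeq2). Rb1 was at 33.9 ± 14.1 and 10.8 ± 9.97 CPM, a log2 fold change of 1.64 (SE 0.75), and 2.67 without PRM library 4, which held the highest PRM level (22.2 CPM). Trp53 was at 21.6 ± 2.79 and 24.0 ± 3.73 CPM.

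**Figure D1:**
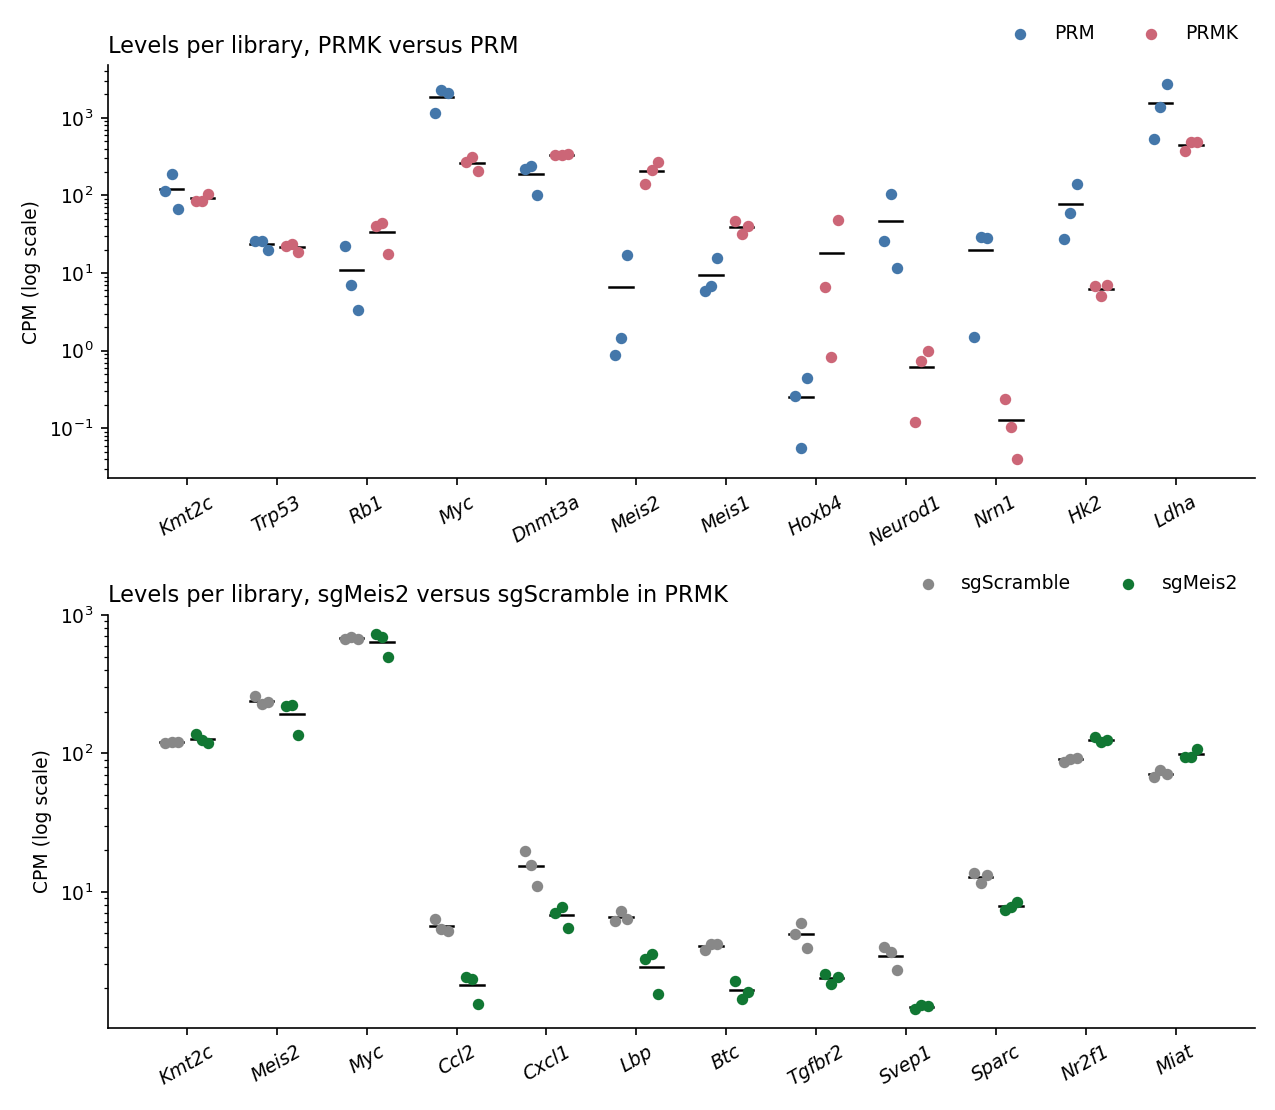
Expression in CPM (log axis) of named genes in each of the 12 RNA libraries, with the mean of each group of 3. Meis2 lay between 139 and 272 CPM in the PRMK libraries and at 17.3 or less in the PRM libraries, and at 137 to 224 CPM in the sgMeis2 libraries and 227 to 259 in the sgScramble libraries.

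Other homeobox genes were also among the genes called higher by DESeq2. Meis1 was at 39.7 ± 7.59 CPM in PRMK and 9.45 ± 5.41 in PRM, a log2 fold change of 2.07 (SE 0.46; adjusted p = 0.19 by edgeR, 0.00219 by DESeq2). Hoxb4, a segment identity gene, was at 6.55, 0.835 and 47.7 CPM in PRMK libraries 1 to 3 and at 0.445 CPM or less in the PRM libraries, with a log2 fold change of 6.19 that was 3.82 without PRMK library 3. Tgif2, a homeobox repressor of TGF-beta signalling, was called lower by DESeq2, at 1.24 ± 0.328 against 9.13 ± 4.75 CPM. Of the 10 tested members of the Meis and Pbx list, 9 had a log2 fold change above 0. The list rose by camera with a preset correlation (adjusted p = 0.0336, median log2 fold change 0.64), and 3 members passed when adjusted over the list alone, of which Meis1 and Meis2 were higher and Tgif2 lower. Its adjusted p = 0.738 with an estimated correlation, and 0.112 without PRM library 4. Of the Hox list, fewer than 4 members were expressed enough to be tested.

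Some genes had no counts in any PRM library. Against a floor of 3 counts over the group, Ppp1r3a was at least 291-fold higher in PRMK, the progesterone receptor gene Pgr at least 155-fold, the protocadherin Pcdha1 at least 134-fold, the sperm gene Spaca1 at least 76.6-fold and the potassium channel gene Kcna4 at least 72.7-fold. Rhox4a and Rhox4a2 were at least 103-fold and 102-fold higher, but they are near-identical copies, so the split of reads between them is uncertain. Pgr was at 9.62 ± 1.53 CPM in PRMK. Tfap2b, a transcription factor, was at 288, 0.835 and 95.7 CPM in PRMK libraries 1 to 3 and at 0.0942 ± 0.0895 in PRM. The naming rule required a DESeq2 call, so all 8 were called higher by DESeq2, with adjusted p from 2.84e-11 to 3.23e-06. None was called by edgeR (adjusted p of 0.158 to 0.192).

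Genes at the other end were far lower in PRMK. Nrn1, a neurite growth factor, was at 0.128 ± 0.103 CPM in PRMK and 19.7 ± 15.8 in PRM. Hapln4, a brain matrix link protein, was at 1.33 ± 0.571 against 41.5 ± 17.3 CPM, a log2 fold change of -4.95 (SE 0.59). Neurod1 had a log2 fold change of -6.25 (SE 1.22), Plekhs1 of -7.79, Cecr2 of -5.69, Gsto1 of -5.36, Zfhx4 of -5.07 and Ccn2, a YAP target, of -5.01. DESeq2 called all 8 lower, as the naming rule required, and edgeR none. Without PRM library 6 the log2 fold change of Gsto1 was -2.80 and that of Plekhs1 -5.77. Without PRM library 5 that of Neurod1 was -4.90 and that of Cecr2 -4.29. Zfhx4, Nrn1, Cecr2 and Hapln4 passed edgeR when PRM library 4 was left out, with log2 fold changes of -4.37 for Zfhx4 and -6.25 for Cecr2.

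Some of the lowest edgeR p-values belonged to genes outside the fixed naming rule, named after their values were seen. Ncald, a neuronal calcium sensor, was at 24.5 ± 5.63 against 0.857 ± 0.218 CPM, Frem2 at 25.5 ± 1.52 against 1.48 ± 0.439, and the glutamate receptor gene Gria4 at 10.5 ± 2.56 against 0.0361 ± 0.0313. Slc7a5, an amino acid transporter gene, was at 153 ± 23.2 CPM in PRMK and 546 ± 82.9 in PRM. Each had an adjusted p of 0.158 by edgeR and was called by DESeq2.

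Of the fixed gene lists, 13 passed camera with a preset correlation of 0.01, 7 higher and 6 lower in PRMK, and no list passed with an estimated correlation. Other ways to split these libraries into equal groups gave 11 to 18 lists, so the number that passed does not set the genotypes apart. Replication-dependent histone genes had the lowest p: all 13 tested members were above 0 and the list rose, with an adjusted p of 1.25e-04 by camera, 2 members passing when adjusted over the list alone, and an adjusted p = 0.718 with an estimated correlation. Hist1h2bc was at 190 ± 27.3 CPM in PRMK and 39.6 ± 22.1 in PRM, and H1f2 at 166 ± 37.8 and 32.1 ± 18.9. Both were called higher by DESeq2. This list passed in each of the 6 analyses that left out a library, with a highest adjusted p of 0.00395 by camera. Leaving out single libraries cannot show a difference in library preparation between the groups, so such a difference stays open. For the 12 other lists that passed, adjusted p = 0.738 with an estimated correlation.

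Lists of cell identity moved together with single PRM libraries. Neuroendocrine genes rose in PRMK by camera (28 tested, 23 above 0, adjusted p = 0.00284), none passed when adjusted over the list alone, and the adjusted p was 0.430 without PRM library 6. In that library Chga was at 3.56 CPM and Syp at 6.77, against at least 634 CPM for Chga and 122 for Syp in the other 5 libraries. Within the list, Stmn2 was called higher by DESeq2 (23.8 ± 13.5 against 1.30 ± 1.39 CPM) and Neurod1 lower. Non-neuroendocrine and Notch-YAP genes fell: all 11 tested members were below 0, with an adjusted p of 0.00685 by camera and 2 passing when adjusted over the list alone, but 0.296 without PRM library 6, where Notch1 was at 66.2 CPM against 5.12 or less elsewhere. Jag1, a Notch ligand, was at 11.1 ± 2.00 CPM in PRMK and 38.4 ± 21.2 in PRM. Epha2 was at 1.65 ± 1.33 CPM in PRMK and at 0.366, 7.74 and 133 in PRM libraries 4 to 6, so the groups overlapped, and its log2 fold change of -4.82 was -1.29 without PRM library 6. Both were called lower by DESeq2. Epithelial genes rose (26 of 28 above 0, adjusted p = 9.64e-04 by camera, none when adjusted over the list alone), with 0.0588 without PRM library 5. Cdh1 was at 0.941, 11.8 and 399 CPM in PRM libraries 4 to 6, and Epcam at 4.65, 5.21 and 396, so the PRM libraries differed among themselves.

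One-carbon and S-adenosylmethionine genes and hypoxia and glycolysis genes fell in PRMK by camera, and neither list passed without PRM library 6, which had the highest mean of both. In the first, PRM library 4 lay below all PRMK libraries (mean log2 CPM 5.08 against 5.21 to 5.42), and in the second PRM library 5 did (5.76 against 5.97 or more). The first list had 22 of 28 members below 0 (adjusted p = 0.00284 by camera, median log2 fold change -0.87), with 3 passing when adjusted over the list alone, Mthfd1l and Ahcy lower and Mat1a higher, and an adjusted p of 0.127 without PRM library 6. Mthfd1l, a mitochondrial folate enzyme, was at 36.6 ± 4.99 CPM in PRMK and 126 ± 67.8 in PRM, and Ahcy, which clears S-adenosylhomocysteine, at 119 ± 14 and 236 ± 50.9. Both were called lower by DESeq2. Mat1a, the liver form of the S-adenosylmethionine synthetase, was called higher, at 10.6 ± 4.83 against 0.23 ± 0.275 CPM. The second had 19 of 22 members below 0 (adjusted p = 0.012 by camera, 1 passing when adjusted over the list alone), with 0.740 without PRM library 6. Hexokinase gene Hk2 was at 6.30 ± 1.08 against 76.5 ± 59.0 CPM and Ldha at 449 ± 67.3 against 1540 ± 1102, both called lower by DESeq2, and Ldha had a log2 fold change of -1.78 that was -1.08 without PRM library 6. Cell cycle genes fell slightly, with 25 of 30 below 0 and a median log2 fold change of -0.21 (adjusted p = 0.0264 by camera, none when adjusted over the list alone, 0.316 without PRM library 5). The mitotic kinase Bub1 was at 48.2 ± 4.10 against 105.3 ± 33.9 CPM.

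The remaining lists that passed were immune, germline and stress lists. Myeloid and lymphoid genes rose (15 of 16 above 0, adjusted p = 0.00561 by camera), with 0.0736 without PRM library 5 and 0.0865 without PRM library 6. Interferon genes rose (15 of 21 above 0, 0.0336), with 0.122 without PRMK library 3 and 0.577 without PRM library 5. Stat2 was called higher by DESeq2, at 33.6 ± 1.73 against 12.8 ± 4.82 CPM. Germline genes that DNA methylation silences rose (4 of 6 above 0, 0.0497), with 0.135 without PRM library 5 and 0.296 without PRM library 6. Xlr3a was at 10.8 ± 8.71 against 0.235 ± 0.224 CPM, and it was the 1 member to pass when adjusted over the list alone. Mitochondrially encoded genes fell (12 of 13 below 0, 0.0377), while mt-Atp8, which overlaps mt-Atp6 so that its reads are uncertain, was called higher by DESeq2 (16 ± 2.72 against 2.54 ± 1.95 CPM). The list had an adjusted p of 0.527 by camera without PRM library 6, and also missed the threshold without PRMK library 3. Heat shock and early response genes fell (10 of 13 below 0, 0.0497), with 0.132 without PRMK library 3 and 0.527 without PRM library 6. In the myeloid, interferon, mitochondrial and heat shock lists, no member passed when adjusted over the list alone.

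The other lists did not pass camera. The adjusted p was 0.0708 each for sex-linked genes, MHC class I genes and imprinted genes, 0.315 for H3K4 methyltransferase complexes, 0.358 for lung cell markers and 0.425 for mesenchymal transition. It was 0.430 for fibroblast genes (direction up, median log2 fold change -0.18), 0.433 for endothelial genes, 0.451 for the DNA methylation machinery, 0.483 for cholesterol synthesis and 0.489 for metastasis and migration genes. It was 0.490 for gut and liver genes, 0.662 for the stress and unfolded protein responses, 0.783 for the driver genes, 0.892 for Polycomb and 0.959 for p53 targets (direction down, median 0.01). Adjusted over the list alone, 3 imprinted genes (Cdkn1c higher, Kcnq1ot1 and Ube3a lower), 2 driver genes (Meis2 higher, Myc lower) and 1 gene each of the endothelial and the metastasis lists passed. DESeq2 called single members of these lists, among them the imprinted genes Cdkn1c higher (17.8 ± 2.27 against 4.30 ± 1.86 CPM) and Dlk1 lower (0.360 ± 0.379 against 8.21 ± 9.52, log2 fold change -4.48, and -2.88 without PRM library 5). It called the neuropilin Nrp2 lower (31.3 ± 11.2 against 233 ± 89.1) and the adhesion gene L1cam higher (96.8 ± 21.2 against 25.4 ± 20.1). Fewer than 4 red blood cell genes were tested.

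**Figure D2:**
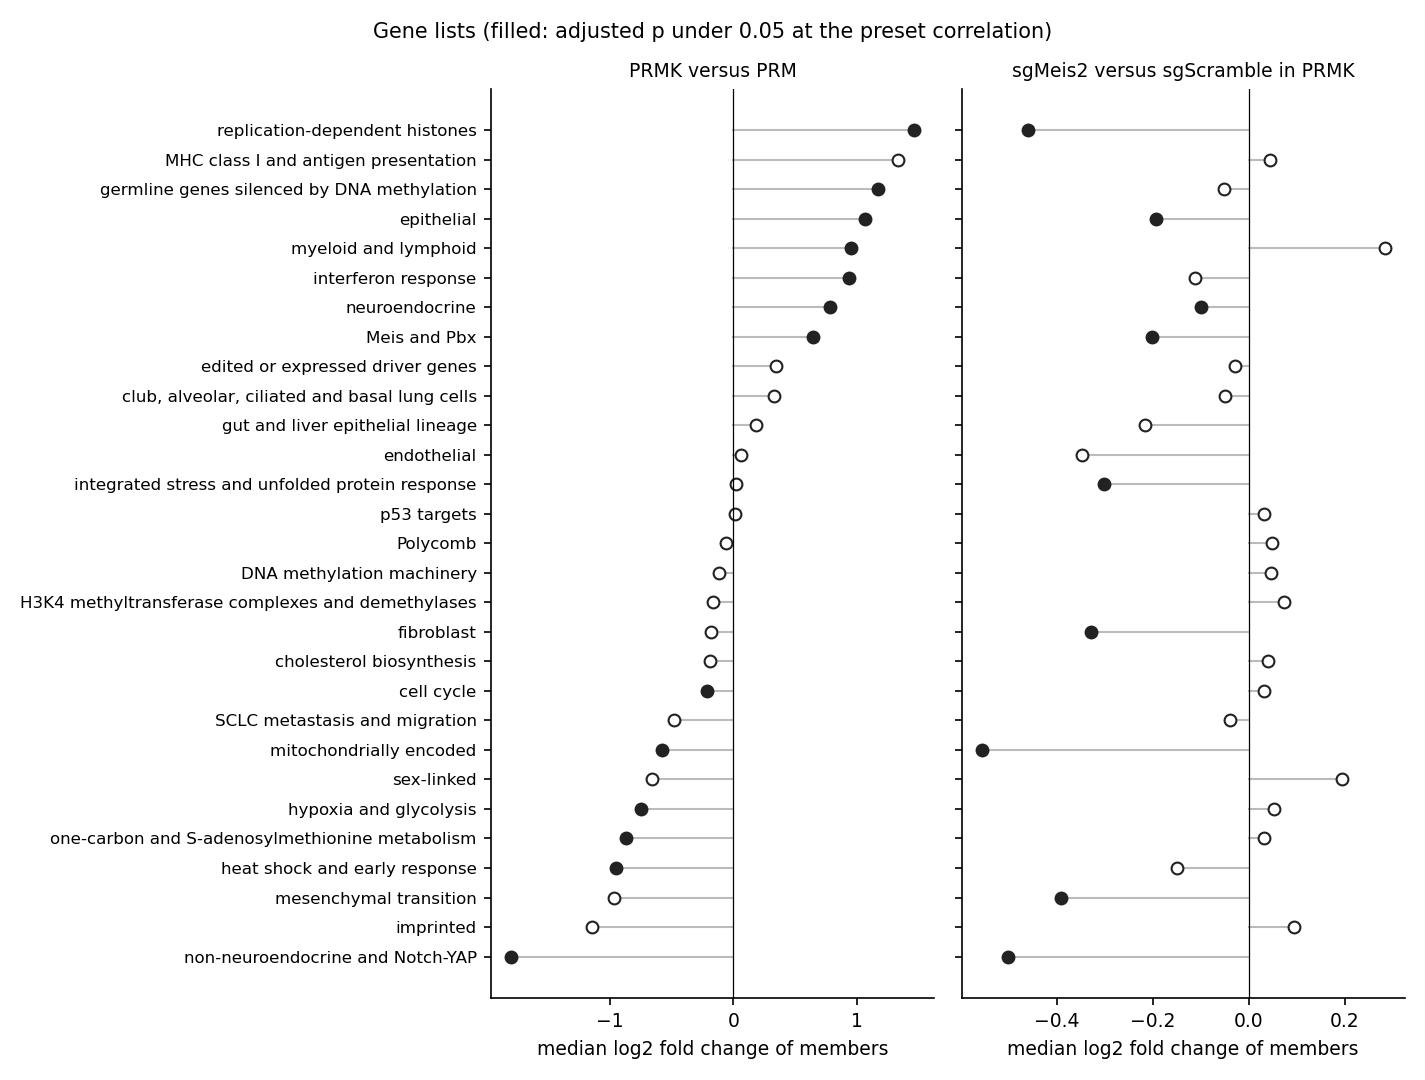
Median log2 fold change of each gene list (horizontal axis) in both RNA comparisons, with lists that passed camera at a preset correlation marked. Of the lists that passed, 7 lay above 0 and 6 below 0 in PRMK versus PRM, and all 9 lay below 0 in sgMeis2 versus sgScramble.

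Libraries of both genotypes also differed along chromosomes. In PRM library 4 the 655 expressed genes of chromosome 5 had a median log2 ratio of -0.88 to the other 5 libraries, with 94.5% of genes below 0, and the 344 genes of chromosome 14 had -0.72, with 92.2% below 0. In PRM library 5, chromosome 13 had a median of 0.64. Chromosome 14 had medians of 0.24, 0.25 and -0.26 in PRMK libraries 1 to 3. Each had a permutation p of 0.0001, the smallest that 10000 permutations can give, and an adjusted p of 0.000444 over 120 tests by permutation. In PRMK versus PRM, the log2 ratio of mean CPM (1 CPM added) was taken less its median over all genes. It had a median of 0.23 over chromosome 5 and 0.19 over chromosome 14, and of 0.01 and 0.04 without PRM library 4. Of the DESeq2 calls with a known chromosome, 107 were higher and 8 lower on chromosomes 5 and 14. On the other chromosomes 429 were higher and 663 lower, so the higher calls partly follow these chromosomes.

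**Figure D3:**
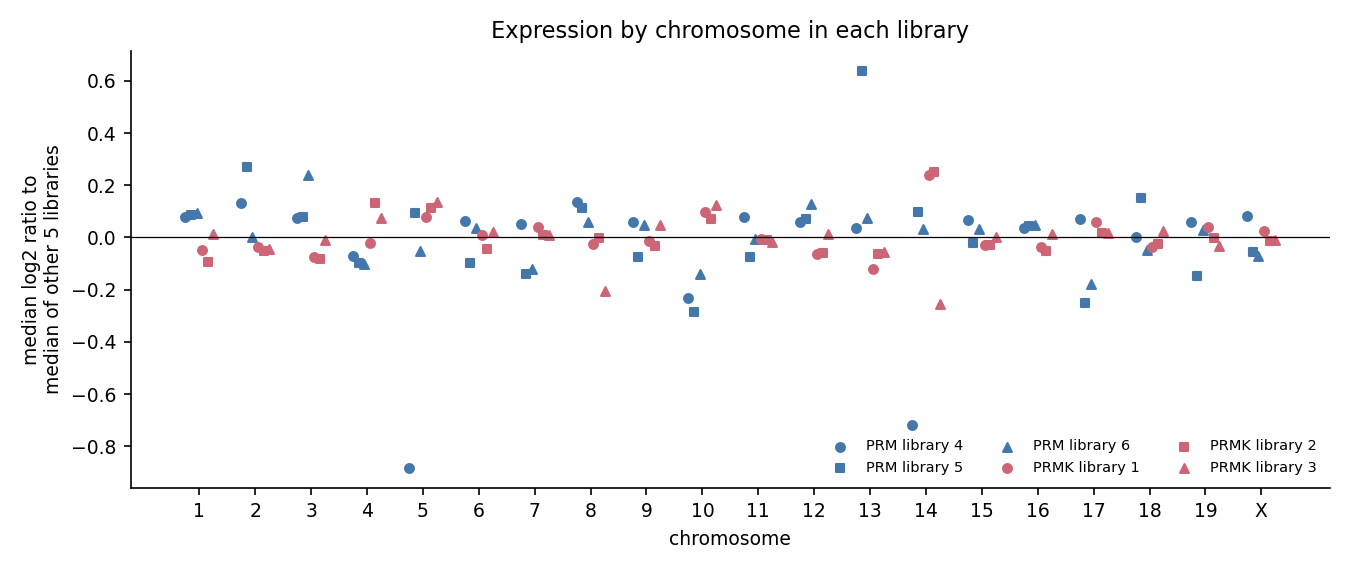
Median log2 ratio of each chromosome's genes in each of the 6 PRMK and PRM libraries to the median of the other 5. PRM library 4 lies at -0.88 for chromosome 5 and -0.72 for chromosome 14, and PRM library 5 at 0.64 for chromosome 13.

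To ask which transcripts depend on Meis2 in PRMK cells, sgMeis2 was compared with sgScramble. Meis2 transcripts were at 193 ± 49.2 CPM (SD, n = 3) with sgMeis2 and 240 ± 16.8 with sgScramble, a log2 fold change of -0.31 (SE 0.19) that edgeR did not call (adjusted p = 0.754; 0.882 by DESeq2) and that was -0.12 without sgMeis2 library 3. The sgMeis2 libraries held 219, 224 and 137 CPM, all below the lowest sgScramble library (227). Among genes called lower by DESeq2, Ccl2 was at 2.10 ± 0.478 against 5.62 ± 0.636 CPM, Cxcl1 at 6.74 ± 1.15 against 15.5 ± 4.36, and Cxcl5 at 27.2 ± 3.28 against 48.0 ± 4.96. Epas1, a hypoxia-responsive transcription factor also called lower, was at 9.06 ± 1.79 against 18.8 ± 1.91 CPM. Nr2f1, a nuclear receptor, was called higher, at 125 ± 5.68 against 90.5 ± 3.52 CPM.

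DESeq2 called 22 of 16260 genes, 3 higher and 19 lower. The edgeR quasi-likelihood test called 0, with 760 genes at an unadjusted p under 0.05 (358 higher, 402 lower) and a lowest adjusted p of 0.677. The edgeR likelihood ratio test called 31 and limma-voom with library weights 67. In simulated data with a single spread per gene and no library set apart, 43 of 217 DESeq2 calls were false (19.8%), and edgeR recovered 53 of 70 genes changed by 2-fold. The real sgMeis2 library 3 did stand apart, so these shares need not hold here. The false share depends on how many genes the simulation changed, so it does not estimate the share among the 22 DESeq2 calls. With the replicate number as a block, edgeR called 0 (636 unadjusted), and the numbers did not pair the libraries. Without sgMeis2 library 3, edgeR called 46 genes, 12 higher and 34 lower, 19 of them among the DESeq2 calls. Without sgScramble libraries 1 or 2, DESeq2 called 0 genes (247 and 287 unadjusted; edgeR 0, with 371 and 408), and 4, 17, 72 and 5 without sgMeis2 libraries 1, 2 and 3 and sgScramble library 3. The authors' table gave 18 genes an adjusted p under 0.05, all of which DESeq2 called here.

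The genes called higher by DESeq2 were Nr2f1 (log2 fold change 0.47, adjusted p = 0.00223), the long noncoding RNA Miat (0.47, 0.0412) and the gene model Gm6034, named here because only 3 were called. Among those called lower, Ccl2 had a log2 fold change of -1.41 (SE 0.21, adjusted p = 2.38e-04 by DESeq2), Epas1 of -1.05, Cxcl1 of -1.19, the matrix protein gene Svep1 of -1.22 and the lipopolysaccharide binding protein gene Lbp of -1.18. The growth factor gene Btc was at -1.07, the TGF-beta receptor gene Tgfbr2 at -1.07 and the membrane repair gene Myof at -1.03. Sparc, a matrix protein gene of the fibroblast list, was at 7.82 ± 0.520 against 12.8 ± 1.15 CPM, a log2 fold change of -0.71. The acute phase genes Saa3 and Cp, chosen after their values were seen, had log2 fold changes of -0.65 and -0.71, and Cxcl5 of -0.82. The driver genes were not called: Kmt2c was at 128 ± 10.1 against 120 ± 1.54 CPM and Myc at 640 ± 126 against 679 ± 15.8. Dnmt3a had a log2 fold change of 0.12, Rb1 of 0.02 and Trp53 of -0.08.

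Of the gene lists, 9 fell by camera with a preset correlation, and none passed with an estimated correlation. Mesenchymal transition genes had 21 of 23 members below 0, a median log2 fold change of -0.39, an adjusted p of 1.07e-08 by camera, 6 members passing when adjusted over the list alone and an adjusted p = 0.0683 with an estimated correlation. Non-neuroendocrine and Notch-YAP genes had 14 of 20 below 0 (6.78e-07, 3 when adjusted over the list alone), fibroblast genes 8 of 9 (3.02e-05, 3 when adjusted over the list alone) and epithelial genes 21 of 24 (3.05e-04, 2 when adjusted over the list alone). For these 3 lists, adjusted p = 0.0816 with an estimated correlation. Replication-dependent histone genes had 13 of 14 below 0 (2.31e-04, none when adjusted over the list alone; adjusted p = 0.365 with an estimated correlation).

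The other lists that fell lost their call without single libraries. All 12 mitochondrially encoded genes were below 0 (adjusted p = 4.73e-04 by camera, none when adjusted over the list alone), with 0.141 without sgMeis2 library 3. Meis and Pbx genes had 10 of 11 below 0 (0.00952, none when adjusted over the list alone), with 0.191 without sgMeis2 library 3. For the stress and unfolded protein list (13 of 20 below 0, 0.00961, none when adjusted over the list alone) the adjusted p was 0.329 without sgScramble library 1, and the call was also lost without sgMeis2 library 1 or 2. For these 3 lists, adjusted p = 0.498 with an estimated correlation. Neuroendocrine genes (21 of 29 below 0, 0.0101, 1 when adjusted over the list alone; adjusted p = 0.369 with an estimated correlation) passed in 1 of the 6 analyses that left out a library, the one without sgMeis2 library 2, with a highest p of 0.0686 without sgScramble library 2. In sgMeis2 library 3, mitochondrially encoded genes made up 0.435% of CPM, against 3.39% to 3.63% in the other 5 libraries.

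Camera did not call the remaining lists in this comparison. The adjusted p was 0.105 each for endothelial and for heat shock genes, 0.120 for H3K4 methyltransferase complexes, 0.141 for sex-linked genes, 0.195 for myeloid and lymphoid genes and 0.236 for interferon genes. It was 0.408 for gut and liver genes and 0.414 each for Polycomb, cholesterol synthesis, lung cell markers, imprinted genes, metastasis and migration genes and the DNA methylation machinery. It was 0.421 for cell cycle, 0.658 for hypoxia, 0.678 for p53 targets, 0.742 for one-carbon metabolism, 0.850 each for drivers and MHC class I, 0.919 for Hox genes (direction up, median -0.01) and 0.937 for germline genes. Adjusted over the list alone, 1 metastasis gene, Tgfbr2, passed. Fewer than 4 red blood cell genes were tested.

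Genes that went opposite ways in these comparisons were then counted. Of 12885 genes tested in both, 0 were called in both by edgeR. By unadjusted p under 0.05, 83 genes passed in both (about 101 would overlap by independence), and DESeq2 called 1 gene in both, Cxcl5, which was lower in PRMK and lower with sgMeis2. Of the 83, 60 went opposite ways, 32 of them higher in PRMK and lower with sgMeis2 (odds ratio 0.149, 2-sided Fisher exact p = 6.34e-05). Across all genes Spearman's rho was -0.065, and genes are not independent replicates.

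In order to locate changes in H3K4 methylation, CUT&Tag peaks of lung PRMK were compared with those of lung PRM. The Hoxb cluster (mm10, chromosome 11, 96194316 to 96368254) had no H3K4me3, H3K4me2 or H3K4me1 peak in either PRM library. In PRMK libraries 1 and 2, H3K4me3 peaks covered 50.2% and 50.2% of it, H3K4me2 peaks 51.0% and 50.9%, and H3K4me1 peaks 35.9% and 24.5%. The Hoxd cluster (chromosome 2, 74668225 to 74765142) went the other way for H3K4me3, with 20.6% and 62.4% covered in PRM and none in PRMK. Over Meis1 (chromosome 11, 18880428 to 19019651), H3K4me1 peaks covered 78.4% and 60.2% in PRMK against 14% and 13.4% in PRM. Over Meis2 (chromosome 2, 115861264 to 116067537), they covered 40.3% and 22.2% against 6.14% and 5.20%. The other marks over Meis2 separated less. H3K4me2 was at 34.9% and 33.3% against 28.0% and 3.60%, and H3K4me3 at 20.7% and 15.4% against 15.1% and 3.78%. For both of these marks, PRMK library 1 lists a guide against Meis2 itself and library 2 a scrambled guide, so they are not plain replicates.

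**Figure D4:**
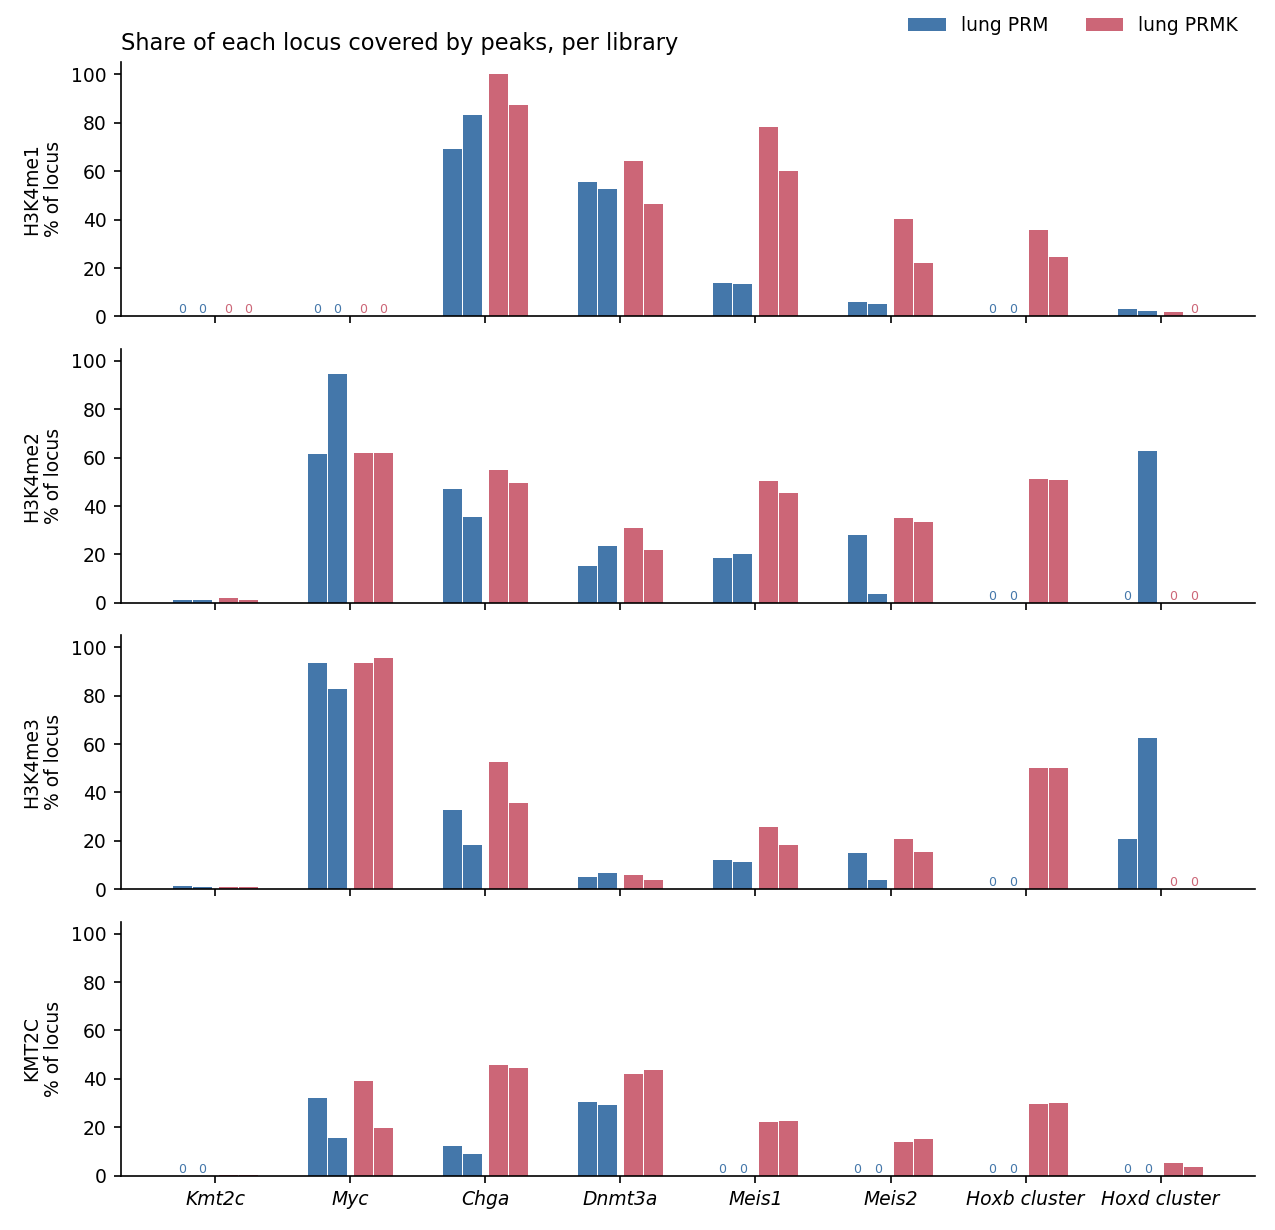
Percent of each named locus covered by peaks in each library of lung PRM and lung PRMK, for the histone marks and KMT2C, libraries 1 and 2 side by side. At the Hoxb cluster H3K4me3 covered 50.2% in each PRMK library and 0% in each PRM library.

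Other loci differed less. H3K4me3 peaks covered 1.08% and 1.09% of Kmt2c (chromosome 5, 25271795 to 25498855) in PRMK and 1.27% and 1.09% in PRM. Over Dnmt3a (chromosome 12, 3801559 to 3914443), H3K4me1 covered 64.3% and 46.5% against 55.6% and 52.7%. Over Myc, H3K4me3 covered 93.4% and 95.6% against 93.3% and 82.6%. Over Chga, it covered 52.5% and 35.6% against 32.9% and 18.3%.

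Across the genome H3K4me1 had the most gained and lost regions among the histone marks. Of 51793 union regions, 8075 carried H3K4me1 peaks in both PRMK libraries and in neither PRM library (gained), 7292 the reverse (lost), and 12778 in all 4. The other 2 ways to split the 4 libraries gave 812 and 405 regions in total. With a reciprocal overlap of 0.5 required between peak and region, more regions were lost than gained, with 4451 gained, 9232 lost and 3293 kept. For H3K4me2, 2912 regions were gained and 489 lost of 36088, against 879 and 985 in the other splits, and without PRM library 1 there were 4643 gained and 3457 lost. For H3K4me3, 293 were gained and 743 lost of 23220, against 458 and 646. These are counts without a test, since an exact permutation test of 2 libraries against 2 cannot give a p under 0.333. With a single library left in 1 group, the H3K4me2 and H3K4me3 totals were 4207 to 10712 and 1893 to 6160. The balance turned for H3K4me3 without PRMK library 2 (1090 gained, 803 lost), and without PRM library 1 the lost regions numbered 5421. For H3K4me1, 8538 were gained and 10287 lost without PRM library 2, and 15866 and 17265 were gained without PRMK libraries 1 and 2. The H3K4me1 lists differed by group, with 38075 and 36911 peaks and a median top signal of 21 and 15 in PRMK. The PRM lists held 30399 and 27746 peaks with 28 and 28. PRMK library 2 covered 77.4 Mb against 148 Mb in PRMK library 1, so differences in calling cannot be told apart from genotype.

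**Figure D5:**
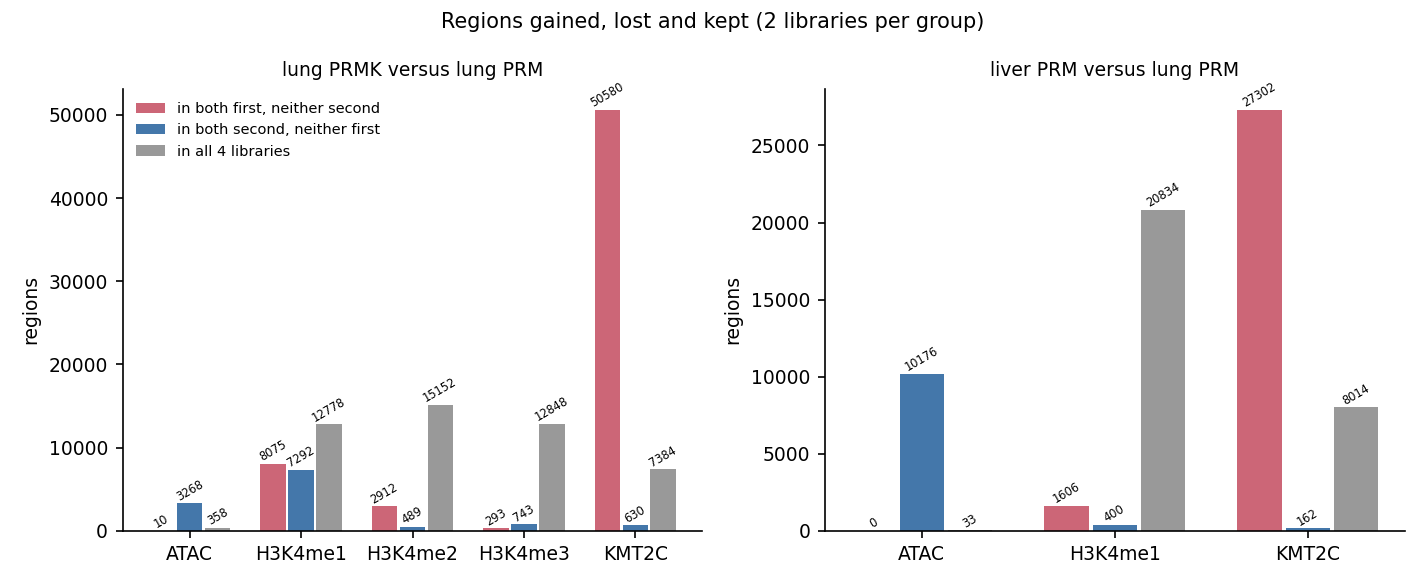
Number of regions with peaks in both libraries of the first group and neither of the second, the reverse, and in all 4 libraries, per mark, for lung PRMK versus lung PRM and liver PRM versus lung PRM. H3K4me1 in PRMK versus PRM had 8075 gained, 7292 lost and 12778 kept regions.

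Promoter status was then set beside expression. Genes with H3K4me3 gained within 1 kb of a gene end, and no lost or kept region there, were expressed higher in PRMK. Their 65 log2 fold changes had a median 1.251 above that of 11341 genes with the mark in all 4 libraries and no gained or lost region. The difference had a permutation p of 1e-05, the smallest possible, and 45 of the 65 lay above 0. Hoxb4 and Pcdha1 were among them. Clustered protocadherins, whose genes share an end, made up 18 of the 65, and the difference over the other 47 was 0.82 (permutation p = 1e-05). A gene silent in PRM entered the test only if PRMK libraries expressed it. The filter on low counts can thus raise both differences, and the permutation does not correct for that. For 97 genes with H3K4me3 lost, the difference was -0.04 (permutation p = 0.657). Among them Nrn1 was lower in PRMK, while Mat1a and Ppp1r3a were higher.

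Genes near changed H3K4me1 regions differed by less. Genes near both a gained and a lost region were left out here. Meis1, Meis2 and Hoxb4 were among 3034 genes with a gained and no lost region within the gene or 10 kb of it. The median log2 fold change of the 3034 was 0.16 above that of 908 genes with only kept regions (permutation p = 2e-05, with 58.2% above 0 against 49.3%). Nrn1, Zfhx4, Dlk1 and Jag1 were among 1624 genes with a lost and no gained region. The median of the 1624 was -0.16 from that of the kept genes (permutation p = 2e-05, with 42.0% above 0). Without PRM library 5, on the ratio of mean CPM, the latter difference was -0.04 and no longer passed. These tests run across genes, which are not independent replicates, and the reference gave no strand, so both gene ends counted as promoters.

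KMT2C peaks, intended to mark where the product of the edited gene binds, were more numerous in the libraries labelled PRMK than in those labelled PRM. Over the Hoxb cluster they covered 29.8% and 30.2% in PRMK and none in PRM, over Meis1 22.2% and 22.5% against none, and over Meis2 13.9% and 15.3% against none. Over Chga they covered 45.6% and 44.5% against 12.4% and 8.82%. Dnmt3a was covered in both genotypes, at 42.0% and 43.7% in PRMK and 30.3% and 29.3% in PRM. The PRMK lists held 187682 and 134561 peaks and the PRM lists 9949 and 16681.

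Of 243721 union regions, 50580 had KMT2C peaks in both PRMK libraries and neither PRM library, 630 the reverse and 7384 in all 4, against 649 and 812 regions in the other 2 splits. Without PRMK library 1 or 2, 117866 or 169303 regions were gained. The PRMK peaks had a median width of 651 and 751 bp and a median top signal of 9 and 9, against 1796 and 1509 bp and 27 and 19 in PRM. Of the PRMK peaks 25.4% and 30.5% overlapped H3K4me1 peaks of PRMK, and 11.8% and 12.4% did after a shift of 1 Mb. Of the PRM peaks 62.2% and 57.7% overlapped H3K4me1 peaks of PRM, and 15% and 14% did after the shift. No test of these values was made.

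To ask whether H3K4me1 was lost where KMT2C had been, regions lost in PRMK were compared with regions kept. KMT2C peaks of lung PRM lay on 525 of 7292 lost regions (7.2%) and on 3152 of 12778 kept regions (24.7%), so lost regions carried them less often (odds ratio 0.237, 2-sided Fisher exact p = 3.07e-233 across regions, which are not independent). Kept regions were wider, with a median of 5916 bp against 3008.5 bp, and within deciles of width the odds ratio was 0.498. Of the gained regions, 267 of 8075 carried a PRM KMT2C peak (3.31%).

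Liver PRM tumours were compared with lung PRM tumours to see what differs at the metastatic site. Over Chga, KMT2C peaks covered 55.1% and 46.7% in liver against 12.4% and 8.82% in lung. Over Meis1 they covered 2.71% and 3.8%, over Meis2 3.81% and 6.49% and over the Hoxb cluster 0.773% and 1.84% in liver, against none in lung. Across the genome 27302 of 127074 KMT2C regions were gained in liver and 162 lost, against 768 and 248 in the other splits. The liver lists were longer, with 65201 and 113129 peaks, and 96139 or 49859 regions were gained without liver library 1 or 2. For H3K4me1, 1606 of 39077 regions were gained and 400 lost, while the other splits gave 855 and 1939 regions, so the liver and lung libraries differed about as much within as between tissues. Without liver library 2, 2310 were gained and 2938 lost.

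Open chromatin was compared last. Over Myc, ATAC peaks covered 67.9% and 53% in lung PRMK and 78.7% and 59.0% in lung PRM. Over the Hoxb cluster, they covered 0% and 14.8% in PRMK libraries 1 and 2 and 0.345% and 0% in PRM. The lists were too unlike in size for a count of changes: 593 and 54201 peaks in lung PRMK, 64596 and 19834 in lung PRM, and 345 and 141 in liver PRM, where single peaks were up to 33.0 Mb wide. In PRMK versus PRM, 10 of 90311 regions were gained and 3268 lost, while another split of the same 4 libraries gave 6144, and 32853 were gained and 3269 lost without PRMK library 1. In liver versus lung, 0 of 55901 regions were gained and 10176 lost, against 58 and 8 in the other splits, and no test was made.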

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

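The tests with robust dispersions, likelihood ratios, library weights, symbol matching, width deciles, without protocadherins, DESeq2 with a library left out, and promoter tests with an RNA library left out were chosen only after the results were seen. Over 111 results and 1247 comparisons with an alternative, 989 stayed the same and 140 passed where the main test had not. Of the rest, 56 no longer passed, 53 values moved and 9 reversed. Tests stayed the same when they kept direction and side of the threshold, and counts when they stayed near the main count. Most of the 989 were log2 fold changes of named genes that the main edgeR test did not call. These stayed uncalled, so the 989 do not measure how firm the results are. Where nothing else is said, the cause was not tested. PRMK versus PRM: edgeR called 0 genes (2384 unadjusted) as the main test and with size factors, no filter, at least 5 CPM, a fold of 2 and robust dispersions, and limma-voom with library weights also called 0. DESeq2 called 1218 and the likelihood ratio test 454. With each library left out, edgeR called 0 to 796 (796 without PRM library 4) and DESeq2 215 (without PRMK library 1) to 4060 (without PRM library 4). Library weights moved the median log2 fold change of all genes to 0.105. Of the lists, 13 passed in the main test, 0 with an estimated correlation, 7 at a mean of 5 CPM, where fewer genes are tested, and 7 (without PRM library 6) to 16 with a library left out. Kmt2c ran from -0.711 to 0.019 with a library left out, reversed without PRM library 5. No paired analysis was possible because the replicate numbers of PRMK (1 to 3) and PRM (3 to 5) do not pair. For sgMeis2 versus sgScramble, edgeR called 0 (760 unadjusted), DESeq2 22, the likelihood ratio test 31 and limma-voom with weights 67. The replicate block called 0 (636 unadjusted). With each library left out, edgeR called 0 to 46 (46 without sgMeis2 library 3), DESeq2 0 to 72 and camera 7 to 10 lists. Of 9 lists, 0 passed with an estimated correlation. Uncalled genes reversed: Rb1 at -0.006 without sgMeis2 library 1 (highest 0.062), Myc at 0.064 without sgMeis2 library 3 and 0.048 with library weights, and Trp53 at 0.054 and 0.063 under these settings. Opposite genes numbered 60 by unadjusted p and 0 by DESeq2, against 0 by edgeR. In the upper part of each peak list, which holds fewer peaks, gained and lost regions numbered 2100 for ATAC in PRMK versus PRM, 9197 for H3K4me1, 1692 for H3K4me2, 669 for H3K4me3 and 28378 for KMT2C, and in liver versus lung 985 for H3K4me1 and 16623 for KMT2C. For ATAC in liver versus lung a reciprocal overlap gave 5680, and in PRMK versus PRM it gave 3293 kept H3K4me1 regions in place of 12778 and 2505 kept KMT2C regions in place of 7384. With 1 library left out a region needs fewer peaks, and totals ran from 7161 to 40719 for ATAC, 18014 to 26728 for H3K4me1, 4207 to 10712 for H3K4me2, 1893 to 6160 for H3K4me3 and 53395 to 170322 for KMT2C, and in liver versus lung from 10319 to 53007 for ATAC, 3603 to 8910 for H3K4me1 and 28654 to 96346 for KMT2C. Without each RNA library, genes with H3K4me3 lost differed from kept genes by -0.152 to 0.222 and genes with H3K4me1 lost by -0.19 to -0.044. These values use the ratio of mean CPM in place of the edgeR log2 fold change, so the measure changed along with the libraries. Pseudocount alternatives were not run, since the tables hold counts. Depth was known for the RNA libraries and not for the peak libraries.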

Other observations

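All tests of explanations here were chosen only after the results were seen; the counts of other splits were planned. Peaks over further loci complete the picture of the lung tumours. Over the Hoxa cluster, KMT2C peaks covered 21.7% and 11.5% in PRMK and 0% and 1.65% in PRM, and over the Hoxc cluster 10.6% and 10.6% against none. Over Trp53 they covered 32.4% and 27.0% in PRMK and 17.9% and 17.9% in PRM. H3K4me1 peaks covered 100% and 87.2% of Chga in PRMK and 69.2% and 83.3% in PRM. Syp had no H3K4me1 peak in any lung library, while H3K4me3 peaks covered 25.8% and 29.1% of it in PRMK and 28.2% and 28.9% in PRM.

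The libraries labelled PRMK held more KMT2C peaks than those labelled PRM, although PRMK carries the guide against Kmt2c. Genotype labels swapped in the KMT2C libraries alone are argued against. The strongest PRMK peaks lay on PRMK H3K4me1 regions by at least 15.6 percentage points more than on PRM regions. The PRM peaks differed by -1.6 and -1.0. A swap carried through both assays would give the same values, so it stays open. Peaks added at weak sites, by a lower calling threshold or a higher background, stay a candidate for the excess. At most 30.5% of PRMK peaks lay on H3K4me1 regions against at least 57.7% of PRM peaks. Such a share can fall with the length of a list alone, so it does not decide the cause. Among the 9949 strongest peaks it was 63.9% and 65.4% in PRMK and 62.2% and 61.4% in PRM. In the longer liver PRM lists it was 34.3% and 28.1% on lung PRM regions. KMT2C protein remaining after editing stays open, because no protein level was available. Kmt2c transcripts had a log2 fold change of -0.423, but in the RNA libraries, where editing of Kmt2c is itself open. An antibody that reads other proteins also stays open and was not tested.

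PRM library 4 had lower expression across chromosomes 5 and 14, which hold Kmt2c and Rb1, although Rb1 had its highest PRM level there. A few strongly lowered genes are argued against, since the median log2 ratio stayed at -0.625 or lower without genes that moved by over 1. Chance placement of independent genes is argued against by an adjusted permutation p of 0.000444. Genes are not independent, and chromosomes in other libraries reached the same p, so the test does not single out this library. Fewer copies of both chromosomes in that tumour are a candidate explanation, since all 8 equal segments of these chromosomes had a median of -0.664 or lower. No copy number data were analysed here, and the reason edgeR called 796 genes without this library was not tested.

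The sgMeis2 library 3 stood apart from the other 5. Lower depth is argued against, since it held 97.4% of the counts of the next lowest library. Reads assigned differently between near-identical gene copies may contribute, since its pseudogenes deviated 2.2 times as much as matched coding genes, against at most 1.24 times in the other libraries. Stronger Meis2 loss in that sample stays open. Genes that separate sgMeis2 libraries 1 and 2 from the controls had a median log2 change of 0.357 there in their direction, against 0.412 in those libraries. These genes were picked for that separation, and all sgMeis2 libraries were set against the same controls, so the values cannot decide it.

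The 6 libraries can be split 3 against 3 in 10 ways, the real one included, too few for a share under 0.05. In PRMK versus PRM, edgeR called 0 genes in all 10 splits. Genes with an unadjusted p under 0.05 numbered 2384 in the real split, with 666 as the highest other, so 1 split reached that count. DESeq2 called 1218 genes, with 116 as the highest other, again 1 split. Camera called 13 lists, with 18 as the highest other and 11 as the lowest, and 4 splits gave at least as many, the real one included. In sgMeis2 versus sgScramble, edgeR called 0 genes in all 10 splits. The real and highest other counts were 760 and 430 by unadjusted p, 22 and 0 by DESeq2 and 9 and 5 lists by camera, each reached by 1 split.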
